A study of Mus musculus with 3 samples.

How the data were processed

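3 libraries of 10x Genomics 3' single-cell RNA sequencing were used, 2 of cells from E14.5 mouse lung sorted as Epcam+ Icam+ and 1 sorted as Epcam+. Groups and replicate numbers were taken from the sample labels. The labels number only the Epcam+ Icam+ libraries and name no pool or litter, so libraries were treated as separate samples. The deposited values are UMI counts per gene and barcode. Per the submitters' processing notes the reads were processed with Cell Ranger 2.1.1 against mm10, whereas per the file headers the count matrices came from Cell Ranger 5.0.1 (Epcam+ Icam+) and 3.0.2 (Epcam+). The gene tables behind the counts also differed, with 32285 genes in the Epcam+ Icam+ libraries and 31053 in the Epcam+ library. The first 7 bases of the barcodes took 953 and 957 values in the Epcam+ Icam+ libraries, which shared 950, and 479 values in the Epcam+ library, of which 127 were shared with the first. The lowest count of any barcode was 500 UMIs, so the barcode lists had been thresholded before deposit. The settings of that step and the gene annotation behind each table are not given in the sources used here.

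Genes were joined by Ensembl ID, and the 30406 IDs in every table were kept. IDs found only in the Epcam+ Icam+ tables numbered 1879 and those found only in the Epcam+ library 647, and 597 shared IDs carried another symbol. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 3400, 3167 and 2990 barcodes. Doublet scores came from scrublet as built into scanpy. Its automatic threshold found 0, 1 and 0 doublets and was not used, and the highest-scoring cells were left out at a fixed rate of 0.8% per 1000 barcodes (129, 115 and 88 cells). The median mitochondrial share of the cells kept was 2.90%, 2.81% and 2.17%, and the median number of genes 4080, 4044 and 4695.5. RNA free in the cell suspension was not estimated or removed.

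The libraries were clustered jointly in Python 3.11.15 with scanpy 1.11.5 (igraph 0.11.9): 2000 variable genes, without Icam1, Epcam, mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden resolution 1, with seed 1. A cluster was named for the cell type with the most marker genes raised, where at least 3 were raised by a log2 of 0.5 (pseudocount 5 CPM). It stayed unnamed where its 10 leading genes held more markers of another type, or where its depth was low and none of its markers led. Epithelial clusters of every name were pooled as the epithelium, with unnamed clusters whose most raised list was epithelial. Cluster 2 (457 cells), in which no list had 3 markers raised, was pooled with them. Shares were given with exact binomial intervals of 95%, and levels of single genes with exact Poisson intervals. For shares of cells with a UMI, cells were thinned to 3000 UMIs by drawing without replacement, which left out 228, 252 and 193 shallower epithelial cells. Cell cycle phases were scored with scanpy on the thinned counts.

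Counts were summed over the cells of each library and compared with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The comparisons were Epcam+ Icam+ against Epcam+ in all epithelial cells, in tip-like cells and in airway-like cells, the difference of that difference between the 2 classes with library as a block, and epithelial cells with against those without an Icam1 UMI, thinned, with library as a block. Classes needed at least 50 cells per library, so the alveolar type 1-like cells were not compared. The macrophages, added later with 47 cells in the Epcam+ library, were compared without this minimum. Comparisons of 2 libraries with 1 had 1 residual degree of freedom, and the spread was borrowed across genes. The biological coefficient of variation was 2.69% in epithelium, 3.42% in tip-like cells, 3.73% in airway-like cells and 2.73% in the Icam1 UMI comparison, which had 2 residual degrees of freedom. Genes were also counted with no test where the mean was at least 10 CPM and the log2 difference at least 1 against each of the 2 libraries. With RLE scaling the log2 fold changes in epithelium moved by a median of -0.0204 from those with TMM.

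Gene lists and marker lists were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of 1 comparison, and members were counted past the threshold over all genes and adjusted over the list alone. The test with an estimated correlation has only the 1 or 2 residual degrees of freedom of the comparison. A call lost in it decides neither way. Named genes were Icam1, Epcam and Nkx2-1 and the 12 genes with the largest log2 fold change in each direction (6 within classes) among genes past the threshold, with a mean of at least 20 CPM and the same direction in each library, leaving out gene models, mitochondrial, ribosomal protein and globin genes, a rule also set in advance. Up to 4 members per list with the largest fold change could be named by that rule. Krt8, Sox4, Clu, Ager and Sftpc, the Icam1 UMI list members past the threshold, and Kif11, Mki67 and Anln were named after their values were seen. Not every gene that the rule picked is reported here. Folds against 0 UMIs were bounded with a floor of 3 UMIs. Gene positions, types and overlaps came from GENCODE vM21 (mm10), which held 99.7% of the 32932 gene IDs listed in any table. It held 97.3% of the 1879 IDs found only in the Epcam+ Icam+ tables and 93.5% of the 647 found only in the Epcam+ table.

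As a background for the Icam1 UMI comparison, the same test was run for 20 random genes whose share of cells with a UMI lay within 20% of that of Icam1 (39.5% over the libraries). The same comparison of the sorts in macrophages, and the epithelial minus the macrophage difference, were added after the data were seen. Alternatives covered RLE scaling, no count filter, the Wald test of DESeq2 1.42.0, no removal of doublets, a stricter cell filter (1500 genes, 5% mitochondrial), thinned counts, leaving out each library, no library block, Leiden resolutions of 0.5 and 2, scaling within libraries, other CPM thresholds and all barcodes. Subsets of clusters were added later.

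The tests were checked on simulated counts with 200 changed genes at the depth of each comparison. The simulated dispersion was 0.01, a wider spread than that estimated in the real comparisons, so the recovery given is that in noisier data. Of genes changed 1.5-fold, 2-fold and 4-fold, the tests recovered 40.3%, 92.5% and 100% in epithelium, 20.9%, 86.6% and 100% in tip-like cells, 8.96%, 77.6% and 100% in airway-like cells, 61.2%, 98.5% and 100% in the Icam1 UMI comparison, and 4.48%, 41.8% and 90.9% for the difference between classes. False calls numbered 10 of 165, 1 of 139, 3 of 127, 10 of 183 and 1 of 92. Numerical work used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.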

Results

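Single-cell 3' RNA sequencing was used to measure the epithelium of mouse lungs at E14.5, a stage at which the lung is a branching tree with growing distal tips and more mature proximal airways. Lungs of C57/B6 embryos were pooled, dissociated and stained with antibodies against Epcam, a surface protein of epithelial cells, and Icam1, an adhesion molecule that leukocytes bind. 2 libraries held cells sorted as Epcam+ Icam+ and 1 library held cells sorted as Epcam+, and the comparison between them asks how epithelial cells picked for surface Icam1 differ from epithelial cells taken without that gate. The Epcam+ Icam+ libraries held 4739 and 4531 barcodes with 74170599 and 67843828 unique molecules (UMIs), and the Epcam+ library held 3697 barcodes with 84460347 UMIs. After filtering, 3271, 3052 and 2902 cells remained, with a median of 19586, 19550.5 and 26668 UMIs per cell. The labels do not say whether the libraries of 1 sort came from separate pools of lungs, so the p-values measure only the spread between these libraries, which may be technical. The sorts also differed in the software version in the file headers, in the gene table and in the set of cell barcodes. They differed too in transcripts of the sex chromosomes, as given below, so the pools of embryos may differ. None of these can be separated from the Icam1 gate.

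Icam1 transcripts were found in epithelial cells of each library, at 198 and 191 CPM (counts scaled to the UMIs of the library) after the Icam1 sort and 162 CPM without it. In the edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment, Icam1 differed by a log2 fold change of 0.18 (SE 0.0434, adjusted p = 0.00121, n = 2 and 1 libraries). Of the 3 largest named epithelial classes, alveolar type 1-like cells had the highest Icam1 level, 256 and 243 CPM in the Epcam+ Icam+ libraries, followed by airway-like cells at 217 and 223 CPM and tip-like cells at 188 and 181 CPM. The few endothelium-like cells had 372, 191 and 69.8 CPM. In the Epcam+ library the airway-like cells had 212 CPM and the tip-like cells 155 CPM. Epcam stood at 1031 and 1020 CPM against 937 CPM, a log2 difference of 0.05 (SE 0.0239, edgeR adjusted p = 0.0547). Nkx2-1, the transcription factor that marks the lung epithelial lineage, differed by -0.16 (SE 0.0414, edgeR adjusted p = 0.00243). With each cell thinned to 3000 UMIs, 41.3%, 40.5% and 36.6% of epithelial cells had an Icam1 UMI. Unthinned, these shares were 79.6%, 77.7% and 84.6% at median depths of 18528, 18876 and 26807 UMIs, the opposite order, so no order is read from them. In mesenchyme-like cells, which should lack Icam1 or hold little of it, 2.27%, 3.64% and 10.4% of cells had an Icam1 UMI at median depths of 2170, 2249 and 19211 UMIs. After thinning 0 of 16, 0 of 21 and 0 of 41 mesenchyme-like cells had one, which allows shares of up to 20.6%, 16.1% and 8.60% by exact binomial intervals. In the immune-like cells Icam1 stood at 89.6, 97.9 and 182 CPM. The cells were sorted on Icam1 and Epcam protein, so their transcript levels check the sort and are not a finding. The genes lie on mm10 (GRCm38, GENCODE vM21 annotation) at chromosome 9, 21015985 to 21028817 (Icam1), chromosome 17, 87635979 to 87651129 (Epcam) and chromosome 12, 56531958 to 56536908 (Nkx2-1), all protein-coding.

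Epithelial cells made up 77.7% (exact 95% interval 76.3 to 79.2) and 76.2% (74.6 to 77.7) of the cells of the Epcam+ Icam+ libraries and 95.1% (94.2 to 95.8) of the Epcam+ library. Immune-like cells, most of them macrophages with C1qa, C1qb and Pf4, made up 19.4% and 19.5% against 2.38%. Mesenchyme-like cells numbered 44, 55 and 48 and endothelium-like cells 14, 28 and 11. These shares were not tested. The epithelial share includes cluster 2 (225, 231 and 1 cells), in which no marker list had 3 genes raised. It also includes the 300 cells of cluster 20 of the Epcam+ library, whose leading genes held macrophage and mast cell genes. Taken as Epcam+ minus Epcam+ Icam+, the difference in the epithelial share was 18.1 percentage points, but 6.69 at a clustering resolution of 2. The difference in the immune-like share was -17.1 points, but between -8.52 and -8.03 in 3 other settings of clustering or filtering. The gates and the antibodies that set them can produce such shares, and the Epcam+ library was also the deeper one.

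**Figure D1:**
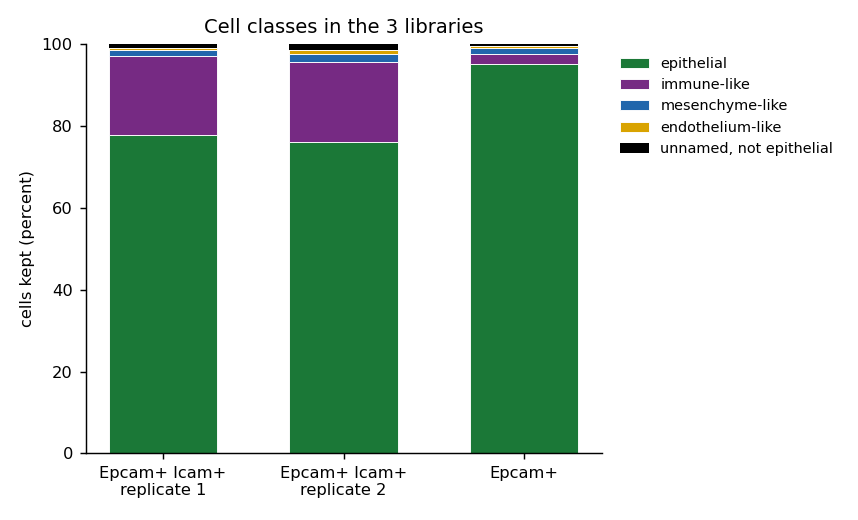
Share of the cells kept (percent, vertical axis) in epithelial clusters, in immune-like, mesenchyme-like and endothelium-like clusters and in unnamed clusters without epithelial genes, with 1 bar per library. Epithelial cells fill 77.7% and 76.2% of the Epcam+ Icam+ bars and 95.1% of the Epcam+ bar.

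Within the epithelium, tip-like cells (Sox9, Etv5, Sftpc) made up 30.1%, 28.4% and 64.3% of epithelial cells, airway-like cells (Sox2, Scgb3a2) 10.4%, 10.5% and 15.04%, and cells of unnamed epithelial clusters 34.4%, 38.3% and 19.6%. Alveolar type 1-like cells, named from Hopx, Ager and Clic5, made up 24.4% and 21.8% of the epithelial cells of the Epcam+ Icam+ libraries and 0.0362% of those of the Epcam+ library, which held 1 such cell. Neuroendocrine-like cells (Insm1) numbered 5, 9 and 30. Ciliated-like cells (Foxj1, Deup1) numbered 13, 13 and 0, and 0 of 2759 cells allows a share of up to 0.134% by the exact binomial interval. The tip-like, airway-like and alveolar type 1-like clusters each came almost wholly from 1 sort, with at most 3 cells of the other. Tip-like cells fell in clusters 0 and 1 of the Epcam+ Icam+ libraries and clusters 12, 19 and 21 of the Epcam+ library, airway-like cells in cluster 3 and cluster 18, and alveolar type 1-like cells in cluster 7. A cluster of 1 library may be that library and not a cell type, and the order of the tip-like and airway-like shares turned with the cell filter or the scaling. With the stricter cell filter the alveolar type 1-like cells made up 32.6%, 32.8% and 25.7% of epithelial cells. The shares of all 3 classes are therefore given per library with no direction. The unnamed cells included cluster 4 of the Epcam+ Icam+ libraries, which had 6 distal tip markers but was led by Hist1h2bc and the surfactant genes Sftpa1 and Sftpb. They also included cluster 20 of the Epcam+ library, with 300 cells whose leading genes came from mast cells and macrophages (Cpa3, Cma1, Lyz2, C1qb), and the low-depth clusters 2, 11 and 15.

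Cell cycle phases, called from transcript scores on cells thinned to 3000 UMIs, differed between the sorts. G1 took 42.7%, 42.9% and 14.0% of epithelial cells, S phase 20.2%, 19.9% and 38.5%, and G2/M 37.1%, 37.2% and 47.5%. Unthinned, G1 took 40.4%, 41.6% and 12.3% and S phase 17.8%, 18.1% and 32.0%, leaving 41.8%, 40.3% and 55.7% in G2/M. Phase calls are relative within the pooled cells and also read free RNA and differences between the libraries, so no rate of division is read from them.

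Across all epithelial cells, alveolar type 1 genes were higher after the Icam1 sort: 6 of 8 rose and 1 fell, with a median log2 fold change of 2.36. Among them were Clic5, a chloride channel of flat alveolar cells, at 5.38 (SE 0.122), Hopx, a transcriptional cofactor of the type 1 lineage, at 3.89 (SE 0.0686), and Ager, a receptor on type 1 cells, at 1.19 (SE 0.0459). Hopx stood at 161 and 147 CPM against 9.83 CPM. Genes of the keratin-high state seen in lung regeneration were higher too, 17 of 20 with 2 lower and a median of 1.09. Examples were the growth factor Areg at 2.86 (SE 0.0573), the urokinase receptor Plaur at 2.78 (SE 0.125) and the TGF-beta-activating integrin subunit Itgb6 at 2.70 (SE 0.0468). Clu was lower at -1.49 (SE 0.0402), Sox4 was lower at -0.29 and the keratin Krt8 differed by 0.37 (SE 0.0285). TGF-beta response genes were higher in 11 of 15 (3 lower), with Pmepa1 at 1.62 and Smad7 at 1.56, which both restrain TGF-beta signalling, and Thbs1 at 1.46. Epithelial junction genes were higher in 11 of 16 (2 lower), with the desmosome gene Dsp at 1.73 and Cldn18 at 1.55, while Cldn6 was lower at -1.63. Of the mitochondrially encoded genes 11 of 13 were higher, led by mt-Nd6 at 3.86.

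All 16 genes of MYC and ribosome biogenesis were lower after the Icam1 sort, with a median of -0.79, among them the spermidine synthase Srm at -2.03 (SE 0.0392) and the nucleolar factor Noc4l at -1.49 (SE 0.0442). Hypoxia and glycolysis genes were lower in 12 of 18 and higher in 3, with Hk2 at -1.59 (SE 0.0318) and Ldha at -1.33 (SE 0.0262) but the angiogenic factor Vegfa at 2.19 (SE 0.041). Cholesterol synthesis genes were lower in 13 of 16 and higher in 1, with Dhcr7 at -1.61 (SE 0.0613) and Nsdhl at -1.33 (SE 0.063). S phase genes were lower in 26 of 40 and higher in 11, with Rrm2 at -1.59 and Mcm2 at -1.42. Immune markers were lower in 7 of 7, led by Tyrobp at -2.44, and the 6 erythroid markers were lower with a median of -4.50 (camera adjusted p = 0.0635), while the Epcam+ library alone held cluster 20 with its macrophage and mast cell genes. Distal tip markers were lower in 6 of 8, such as Etv4 at -2.20 and Id2 at -1.62, with Sftpc higher at 1.24, and Wnt targets in 8 of 12, such as Wnt7b at -2.30. Neither of these 2 lists passed its test (camera adjusted p = 0.0666 for each).

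The list tests used camera with a preset correlation of 0.01 on the edgeR fit, over all lists of the comparison. Adjusted p was 0.0201 for alveolar type 1 markers, 0.000978 for the keratin-high state, 0.019 for the TGF-beta response and for junctions, and 0.0249 for mitochondrially encoded genes. Of the lists that were lower it was 5.1e-05 for MYC and ribosome biogenesis, 0.0118 for hypoxia and glycolysis and for cholesterol synthesis, 0.00188 for S phase and 0.00603 for immune markers. These 10 lists lost their call with correlations estimated from the libraries, each at adjusted p = 0.926 with an estimated correlation. That test rests on 1 residual degree of freedom and can hardly pass. Hypoxia and glycolysis, with an estimated correlation of -0.0588, under the preset 0.01, still went from p = 0.00208 to p = 0.186 by camera. These lost calls therefore decide neither way. Adjusted over the list alone, the counts were the same as over all genes for these 10 lists. The other lists did not pass, among them p53 targets (9 higher and 7 lower of 17), the NF-kB and TNF response (7 and 2 of 19), YAP targets (7 and 4 of 11) and Notch (4 and 4 of 10). FGF and ERK targets (7 and 0 of 11), BMP targets (1 and 6 of 9) and interferon and antigen presentation (3 and 5 of 17) did not pass either. Nor did dissociation stress (9 and 8 of 18), lung transcription factors (7 and 10 of 18), G2/M (20 and 25 of 51), ribosomal proteins (27 and 47 of 84) and alveolar type 2 markers (4 and 3 of 8). Markers of basal (2 higher of 4), ciliated (5 higher and 1 lower of 6), neuroendocrine (1 and 3 of 5), mesenchymal (2 and 1 of 4) and smooth muscle cells (2 higher of 4) did not pass. Nor did those of pericyte (1 higher of 3), endothelial (1 and 1 of 4) and neural cells (1 higher of 3), or airway markers (4 and 3 of 8).

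The same difference was then taken in the macrophages (cluster 5), 526 and 476 cells against 47, which were carried through the same libraries. Of the 30 lists, 25 had medians on the same side of 0 in each cell type. Over the members tested in both cell types, the median log2 fold change of the keratin-high state was 0.93 in epithelium and 0.99 in macrophages, with 16 of 19 members on the same side of 0. It was 1.99 and 1.63 for alveolar type 1 markers, 0.95 and 1.25 for the TGF-beta response, 0.60 and 1.14 for junctions, -1.01 and -0.64 for hypoxia and glycolysis, and -0.59 and -0.31 for S phase. The epithelial genes among these are read at low levels in macrophages: Epcam itself stood at 161, 139 and 83.1 CPM, scaled by TMM, in cluster 5. Free RNA was not removed, so such values may come from epithelial cells of the same library. For lists of epithelial genes, distal tip markers included, the macrophages therefore cannot tell a shared difference from carried-over RNA. Tested as the epithelial difference minus the macrophage difference, MYC and ribosome biogenesis genes were lower in epithelium (8 of 16 lower, camera adjusted p = 2.6e-08), as were distal tip markers (2 of 8 lower, -1.29 in epithelium and 0.02 in macrophages, camera adjusted p = 0.00664). Hypoxia and glycolysis genes (4 of 18 lower, camera adjusted p = 0.0497), S phase genes (5 of 40 lower, 0.0368) and mitochondrially encoded genes (11 of 13 lower, 1.6e-13) passed as well. So did immune markers (7 of 7 lower, 5.4e-18), erythroid markers (1 of 4 lower, 0.00092), ribosomal proteins (53 of 83 lower, 9.6e-13) and the NF-kB and TNF response (2 higher and 7 lower of 19, 0.00664). The lists higher in epithelium than in macrophages were G2/M (9 higher and 1 lower of 51, 3.7e-09), interferon and antigen presentation (2 and 2 of 18, 0.00664) and dissociation stress (6 and 4 of 18, 0.0198). The keratin-high state (0.458), the TGF-beta response (0.191), junctions (0.388) and alveolar type 1 markers (0.388) did not pass, which decides neither way. With an estimated correlation the adjusted p of each of these lists was 0.852.

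**Figure D2:**
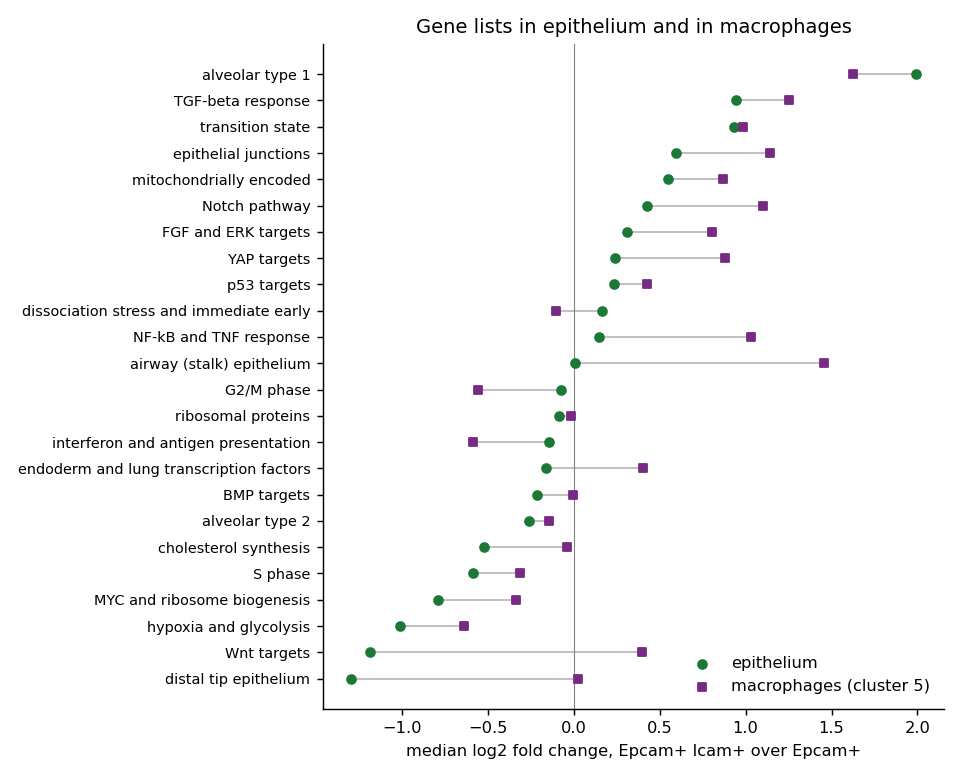
Median log2 fold change of each gene list, Epcam+ Icam+ over Epcam+ (horizontal axis), in epithelial cells (circles) and in macrophages of cluster 5 (squares), joined by a line per list, over the members tested in both cell types. The keratin-high transition state lies at 0.93 in epithelium and 0.99 in macrophages.

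The 12 genes with the largest excess after the Icam1 sort began with Fdx2, a mitochondrial ferredoxin, at a log2 fold change of 9.25 (SE 0.122, edgeR adjusted p = 1.5e-17), with 5 UMIs in all epithelial cells of the Epcam+ library, and the proton pump subunit Atp6v0c at 8.25 (SE 0.0825). They were followed by Rnasek at 7.69, Mrpl53 at 6.80, B3gnt2 at 5.85, the nuclear RNA Neat1 at 5.75, Aarsd1 at 5.70 and Lars2 at 5.59. Next came Adnp at 5.30, the linker histone Hist1h1d at 4.97, AY036118 at 4.93 and the nucleoside diphosphate kinase Nme2 at 4.88. The 12 with the largest deficit began with Amd2 at -7.80 (SE 0.0939, edgeR adjusted p = 5.9e-18), Ptp4a1 at -5.76 (SE 0.0484), followed by Usp50 at -4.18, Chtf8 at -3.96, Coro1b at -3.15, Wdr89 at -3.13 and Taf6l at -2.93. The others were Igfbp4 at -2.83, the mRNA export factor Nxf1 at -2.48, Ftl1-ps1 at -2.39, the complement protease Cfi at -2.30 and Wnt7b, a ligand of the distal epithelium, at -2.30 (SE 0.0334). Amd2 and Ftl1-ps1 are near-copies of other genes, and Hist1h1d belongs to a multigene family, so their counts are uncertain. 9 of the 24 share exonic bases on 1 strand with a gene that is listed in only 1 of the gene tables, namely Fdx2, Rnasek, Mrpl53, B3gnt2, Aarsd1, Adnp, Nme2, Ptp4a1 and Chtf8, and these too are uncertain. In macrophages 24 of 24 genes differed in the same direction and 23 passed the threshold, with Nme2 at 5.599 and Ptp4a1 at -5.37 there, and Igfbp4, a binding protein of insulin-like growth factors, at -0.89. The exception was Cfi at -1.68 (edgeR adjusted p = 0.0821). Wnt7b lies on chromosome 15 (85535437 to 85582473, mm10) and stood at -1.40 in macrophages (edgeR adjusted p = 0.0304), from 112 UMIs in the Epcam+ Icam+ libraries and 14 in the Epcam+ library.

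**Figure D3:**
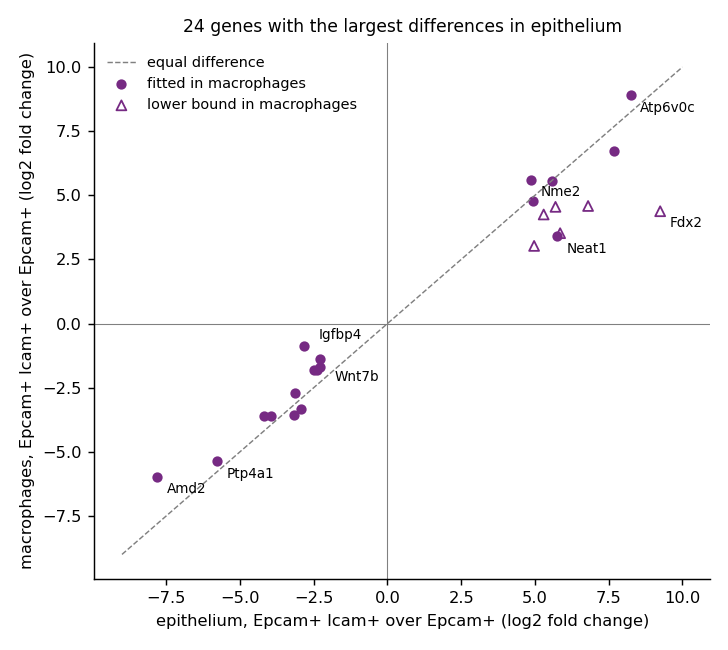
Log2 fold change, Epcam+ Icam+ over Epcam+, of the 24 genes with the largest differences in epithelium (horizontal axis) and in macrophages of cluster 5 (vertical axis). Triangles mark 6 genes with fewer than 3 UMIs in the macrophages of the Epcam+ library, placed at a lower bound of 3 UMIs, and the points lie on the same side of 0 in both cell types for 24 of 24 genes.

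Counted over all genes, 11750 of 14992 tested genes differed in epithelium at an edgeR adjusted p under 0.05, 5946 higher and 5804 lower after the Icam1 sort. With 1 residual degree of freedom the lone Epcam+ library is assumed to vary like the other 2, which differed from each other by a biological coefficient of variation of 2.69%. By size alone, 1779 of 7478 genes with at least 10 CPM differed by at least 2-fold in the same direction against each Epcam+ Icam+ library, 1149 higher and 630 lower, beside 4 genes that differed so between the 2 Epcam+ Icam+ libraries. In macrophages 4392 of 12602 genes differed. Over 12211 genes tested in both cell types the log2 fold changes had a Pearson r of 0.564 across genes, which are not independent replicates. Of the 10252 epithelial calls, 84.0% had the same sign in macrophages. Calls in both cell types numbered 2084 higher and 1845 lower, against 985 and 834 for independent lists, and 168 went opposite ways. These are different cells of the same libraries, so part of the excess may come from the shared libraries. The difference between epithelium and macrophages passed for 1414 of 13818 genes, 195 of them higher in epithelium and 1219 lower. In this joint fit ribosomal proteins had a median of -0.18, beside -0.09 in epithelium and -0.02 in macrophages fitted apart. The counts of genes and list members lower in epithelium may thus depend in part on the scaling, which was not tested. Software version, gene table and barcode set moved with the sort in every one of these counts, as did the sex-linked transcripts given next.

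Genes of the sex chromosomes also differed. Xist, the non-coding RNA of the inactive X chromosome (X, 103460366 to 103483254, mm10), was lower after the Icam1 sort by a log2 fold change of -1.26 (SE 0.0402, edgeR adjusted p = 2.1e-13). The Y-linked genes Ddx3y and Eif2s3y were higher by 1.69 (SE 0.0539) and 1.70 (SE 0.0517). Of the epithelial cells with UMIs from Xist or Y-linked genes but not both, 24.7% (exact 95% interval 22.7 to 26.7) and 21.5% (19.6 to 23.5) of the Epcam+ Icam+ cells had Xist, against 79.7% (77.9 to 81.4) of the Epcam+ cells. The macrophages gave 20.5%, 22.1% and 73.7%. The libraries of the sorts thus differed in this measure in each cell type.

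Within the tip-like cells (766 and 660 cells against 1773), G2/M genes were higher after the Icam1 sort in 37 of 51 and lower in 9, with a median of 0.49 (camera adjusted p = 8.3e-05, and adjusted p = 0.82 with an estimated correlation). Among them were the mitotic motor Kif11 at 2.45, the proliferation marker Mki67 at 2.11 and Anln, which acts in cytokinesis, at 2.03. The tip-like clusters of the Epcam+ Icam+ libraries were led by histone genes (cluster 0) and mitotic genes (cluster 1), and those of the Epcam+ library by mitotic genes (12 and 19) and S phase genes (21), so this value depends on which cells the clusters took. Over all distal clusters the G2/M median was -0.18 (camera adjusted p = 0.342). MYC and ribosome biogenesis genes were lower in 16 of 16 in tip-like cells (median -0.71) and in 12 of 16 in airway-like cells (median -0.64, 264 and 245 cells against 415). The keratin-high state was higher in 15 of 19 (3 lower) and 13 of 20 (4 lower), with medians of 1.02 and 1.06, and alveolar type 1 genes in 7 of 8 and 4 of 7. None of these lists held with an estimated correlation (adjusted p = 0.82 for each in tip-like cells, and 0.839 or more in airway-like cells). The edgeR test called 10609 of 13379 genes in tip-like cells (5363 higher, 5246 lower) and 8008 of 11762 in airway-like cells (4005 higher, 4003 lower), where DESeq2 called 4266. Log2 fold changes in the 2 classes had a Pearson r of 0.888 across 11717 genes. Of the calls, 3722 were higher and 3672 lower in both classes, against 1670 and 1645 for independent lists, again from shared libraries. The 6 largest differences in each direction were in genes also named for the whole epithelium, such as Fdx2 at 9.03 and 10.81 and Amd2 at -8.03 and -6.41, with Galnt2 at 7.06 added in tip-like cells, and the sorts differed in software, gene table and barcodes here too.

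The difference between the sorts was not the same in tip-like and airway-like cells for 1231 of 12457 genes by edgeR (692 with a higher value in tip-like cells, 539 with a lower one), and for 220 genes by DESeq2 (192 and 28). The largest were replication-dependent histone genes: Hist1h2bb at 5.26 (SE 0.537, edgeR adjusted p = 1.3e-06), Hist2h2bb at 5.06, Hist1h3f at 4.75, Hist1h3b at 4.61, Hist1h1c at 4.39 (SE 0.123) and Hist1h2bm at 4.32. Histone genes such as Hist1h2bb also led tip-like cluster 0, and members of this family share sequence, so how far their values follow from the drawing of that cluster is open. Lower in tip-like cells relative to airway-like cells were the growth factor Bmp4 at -1.93 (SE 0.199, edgeR adjusted p = 1.4e-06), the ephrin Efnb2 at -1.44, Mboat1 at -1.40, Fam107b at -1.35, Noct at -1.25 and Adamts1 at -1.22. Bmp4 differed between the sorts by -1.63 in tip-like cells and 0.27 in airway-like cells. As a list, G2/M genes had a higher value in 34 of 51 (median 0.87, camera adjusted p = 4.2e-35; 42 adjusted over the list alone) and S phase genes in 14 of 40 (6.4e-10). So did BMP targets in 2 of 7 (0.0011) and hypoxia and glycolysis genes in 5 of 18 (0.0291), and 3 of 4 erythroid markers had a lower one (0.000213). None of these 5 lists held with an estimated correlation (adjusted p = 0.877 with an estimated correlation).

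The second comparison stayed within each library and set epithelial cells with an Icam1 UMI against those without, all thinned to 3000 UMIs. Software and barcode set thus did not enter. After thinning 41.3%, 40.5% and 36.6% of epithelial cells had an Icam1 UMI, but unthinned 79.6%, 77.7% and 84.6% did. Many cells without a UMI after thinning therefore hold Icam1 transcripts. The split does not part cells that express Icam1 from cells that do not. In cells with an Icam1 UMI the alveolar type 1 genes had a median log2 fold change of 0.25 over 7 members (1 past the threshold over all genes and 5 adjusted over the list alone). The camera adjusted p was 0.000119, and adjusted p = 0.23 with an estimated correlation. Within tip-like cells alone the median was 0.20 (0 of 7 called, camera adjusted p = 0.0398, 0.465 with an estimated correlation). Within airway-like cells it was 0.37 (4 members, 0 called, camera adjusted p = 0.283). Ager was higher by 0.25 (SE 0.0552, edgeR adjusted p = 0.00263) and Clic5 stood at 0.52 (SE 0.16, edgeR adjusted p = 0.0811), with -0.36 in the Epcam+ library. YAP targets had a median of 0.23 (2 of 11 higher, 6 adjusted over the list alone), with Ccn1, a matricellular protein, at 0.28 (SE 0.0363, edgeR adjusted p = 2.4e-09) and Ankrd1 at 0.37 (SE 0.108, edgeR adjusted p = 0.0497), though lower in 1 of 3 libraries at -0.15. The keratin-high state had a median of 0.10, with 3 of 19 higher (9 adjusted over the list alone): the growth factor Hbegf at 0.33, Tnfrsf12a at 0.19 and Sox4 at 0.16. TGF-beta response genes were higher in 3 of 14 (3 adjusted over the list alone), namely Tagln at 0.31, Tgfb2 at 0.24 and Thbs1 at 0.23. Of the junction genes Cldn18 was higher at 0.21 (1 of 15, and 1 adjusted over the list alone), and dissociation stress genes were higher in 3 of 17, with Btg2 at 0.24, and lower in 1, Hspa8 at -0.15 (4 and 1 adjusted over the list alone).

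In cells with an Icam1 UMI, Scgb3a2, a secretoglobin of airway cells (chromosome 18, 43764289 to 43767399, mm10, protein-coding), was lower by -0.98 (SE 0.0741, edgeR adjusted p = 2.8e-22, lower in 3 of 3 libraries). The surfactant genes Sftpa1 and Sftpb were lower by -0.64 and -0.47, giving the alveolar type 2 list a median of -0.47 (2 of 5 lower, 3 adjusted over the list alone). Distal tip markers had a median of -0.19 (2 of 8 lower, 5 adjusted over the list alone), with Sftpc at -0.17 and Id2 at -0.20, and airway markers -0.35 (1 of 8 lower, 3 adjusted over the list alone, and 1 higher there). Without the low-depth clusters, some of which Scgb3a2 led, the median of the airway markers turned to 0.05 over 6 members and the list no longer passed (camera adjusted p = 0.294). Within airway-like cells alone it was -0.35 (1 of 5 lower, 3 adjusted over the list alone) and the list passed. Its camera adjusted p was 4.0e-06, and 0.826 with an estimated correlation. Within tip-like cells the airway markers did not pass (3 members, camera adjusted p = 0.989). G2/M genes were lower in 7 of 51 (19 adjusted over the list alone), with Tubb4b at -0.37 and Psrc1 at -0.50, and the median was -0.15. Within tip-like cells the G2/M median was -0.012 (camera adjusted p = 0.758) and within airway-like cells -0.11 (camera adjusted p = 0.465), so the list passed in neither class. The medians were -0.12 for MYC and ribosome biogenesis (1 of 16 lower, 5 adjusted over the list alone), -0.07 for S phase (0 of 40), -0.05 for ribosomal proteins (0 of 83) and 0.06 for mitochondrially encoded genes (0 of 13, 5 adjusted over the list alone). The counts over the list alone were 0 for S phase and for ribosomal proteins. Globin genes were far lower, with a median of -5.40 over 4 erythroid markers, and 83038 of the 89631 globin UMIs in epithelial cells came from the Epcam+ library, most of them (87.3%) in its low-depth clusters.

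By single genes, 166 of 10362 differed between cells with and without an Icam1 UMI by edgeR (87 higher, 79 lower), and 1241 had an unadjusted p under 0.05. The largest excess was in Hmox1, the heme-degrading enzyme, at 0.60 (SE 0.155, with 0.09, 1.29 and 0.22 in the 3 libraries), Cpm at 0.60, Frmd6 at 0.59, Rec8 at 0.57, the desmosome gene Pkp2 at 0.53, Ces1d at 0.49 and Ptpn14 at 0.48. Others were Myof at 0.45, the chemokine Cxcl16 at 0.44, Kmt2c at 0.43 and Fto at 0.43. The largest deficit after Scgb3a2 and Sftpa1 was in Hist2h2ac at -0.57, Kti12 at -0.56, Hist1h2bj at -0.55, Psrc1 at -0.50, Hist1h2bm at -0.49, Hist1h1d at -0.48, Cytl1 at -0.47, Hist1h1c at -0.47, Sftpb at -0.47 and Hist1h3f at -0.44, of which the histone genes are uncertain as members of multigene families. Camera called 15 lists with a preset correlation, among them, by adjusted p, 1.7e-05 for YAP targets, 1.3e-06 for the keratin-high state, 0.00111 for the TGF-beta response, 2.2e-06 for alveolar type 2 markers and 3.8e-13 for G2/M. FGF and ERK targets (1 of 8 higher, median 0.10, 0.0615), NF-kB (1 of 11 higher), hypoxia and glycolysis (1 of 18 lower) and BMP targets (1 of 7 lower, median 0.01 but test downward) did not pass. Nor did p53, Notch, Wnt, cholesterol synthesis and immune markers (0 called in each), lung transcription factors (0 of 16, median 0.0035 and mean -0.02) or interferon genes (1 of 8 higher, median -0.04 and mean 0.03). Only the erythroid markers held with an estimated correlation (adjusted p = 0.0444), and the others had adjusted p of 0.23 or more with an estimated correlation. Within tip-like cells alone 2 lists that did not pass over the epithelium did pass. These were the NF-kB and TNF response (0 of 8 called, 2 adjusted over the list alone, camera adjusted p = 0.0141) and p53 targets (0 of 12, 0.0398). Each had adjusted p = 0.465 with an estimated correlation. As a background, splits by a UMI of 20 random genes of like detection gave 9 to 912 calls with a median of 24.5, and 3 of the 20 gave at least as many as Icam1. Random genes also reached the list medians of Icam1 for the keratin-high state, the TGF-beta response, junctions and distal tip markers (2 of 20 each), for YAP targets and airway markers (1 of 20 each), for G2/M (2 of 20), for S phase (5 of 20), for ribosomal proteins (4 of 20) and for mitochondrially encoded genes (2 of 20). None of the 20 reached those of dissociation stress (0.082, highest random 0.057) and of MYC and ribosome biogenesis (-0.122, lowest random -0.078). The same held for alveolar type 1, alveolar type 2 and erythroid markers, and for FGF and ERK targets, which did not pass. Without Epcam+ Icam+ replicate 2 the count was 14, without replicate 1 it was 98 and without the Epcam+ library it was 221, and DESeq2 gave 28.

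**Figure D4:**
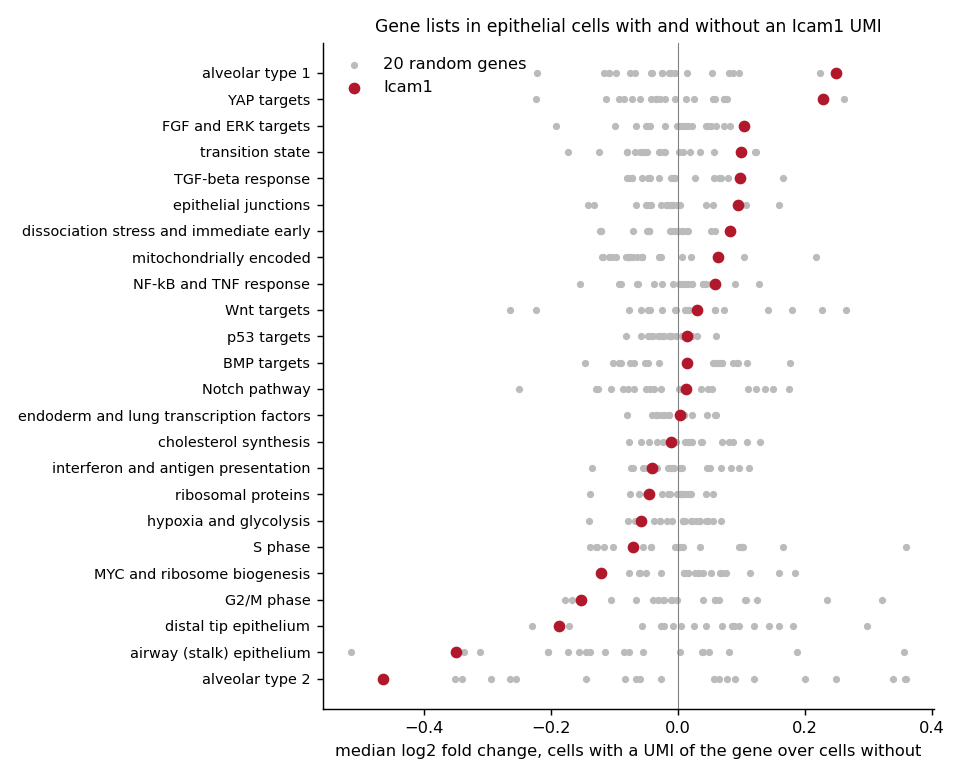
Median log2 fold change of each gene list between epithelial cells with and without a UMI of Icam1 (large points) or of each of 20 random genes of like detection (small points), on the horizontal axis, with 1 line per list. Alveolar type 1 markers for Icam1 lie at 0.25, beyond the highest random gene at 0.22, and alveolar type 2 markers at -0.47, beyond the lowest at -0.35. Dissociation stress, FGF and ERK targets and MYC and ribosome biogenesis also lie beyond the random genes.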

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

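Of the tests below, the ratio to macrophages and the test on cells with an Icam1 UMI were chosen only after the result was seen, as were the Icam1 UMI values within classes, and the macrophage comparison itself was added after the data were examined.

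A test of the difference between groups singled out 1231 genes whose sort difference was not the same in tip-like and airway-like cells, and 1414 genes whose sort difference was not the same in epithelium and macrophages. The named genes of the first set, by log2 difference between tip-like and airway-like cells, were Hist1h2bb (5.26), Hist2h2bb (5.06), Hist1h3f (4.75), Hist1h3b (4.61), Hist1h1c (4.39), Hist1h2bm (4.32), Bmp4 (-1.93), Efnb2 (-1.44), Mboat1 (-1.40), Fam107b (-1.35), Noct (-1.25) and Adamts1 (-1.22). A signal in data that the comparisons left aside was the share of UMIs on genes outside the shared table, 0.478% and 0.478% in the Epcam+ Icam+ libraries and 0.0763% in the Epcam+ library.

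The first pattern weighed was the 24 genes with the largest differences between the sorts. The values gave no clear reading of the Icam1 sort as their cause. For 23 of them the log2 fold change between cells with and without an Icam1 UMI was signed by their direction between the sorts. The median was 0.029 (SD 0.2, 13 of 23 positive), too small beside its spread to decide. An Icam1 UMI is also a weak stand-in for surface protein, and many cells without one after thinning had one unthinned. A difference between the libraries that acts on every cell type fits: the median ratio of the macrophage to the epithelial log2 fold change was 0.801 (quartiles 0.658 and 0.941), or 0.922 without the floor of 3 UMIs, a value seen before the floor was added. Gene models that differ between the gene tables may account for part, since 37.5% of the 24 genes (9) share exonic bases on 1 strand with a gene listed in only 1 table, against 2.08% of 5039 other genes (Fisher's exact p = 1.07e-09). For the other 15 genes the cause stays open between software, chemistry, free RNA and biology common to both cell types, because each of these moved with the sort.

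The second pattern was the higher Y-linked genes and lower Xist after the Icam1 sort. Counting of Xist as the cause is argued against, since in cells with Xist alone its level in the Epcam+ library was 0.643 times that in the Epcam+ Icam+ libraries, when this explanation needed more. Pools of embryos with different shares of males and females fit, as cells with Xist alone made up 79.7% of the Epcam+ cells with either signal (95% interval 77.9 to 81.4, n = 2041) against 24.7% and 21.5%. The values of Xist and the Y-linked genes over whole libraries had been seen when this test was written. Which other genes differ through the sex of the embryos was not tested, so part of the sort difference could come from the pools.

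The third pattern was the set of gene lists that differ between cells with and without an Icam1 UMI. For alveolar type 1 markers a split by a UMI of any gene is argued against only weakly. Of 20 random genes 0 gave a median as high, but the highest, at 0.22, lay close to Icam1 at 0.25. With 20 genes this explanation is not excluded. The count was also 0 for dissociation stress genes, so it is not particular to alveolar type 1 markers. For G2/M genes 2 of 20 random genes gave a median as low as that of Icam1, which decides neither way. Red blood cell RNA in shallow barcodes could explain part of the globin difference: 86.1% of the globin UMIs of thinned epithelial cells lay in low-depth clusters, and random genes gave an erythroid median of -2.68 (lowest -4.46), yet without those clusters 4 of 4 globin genes stayed lower, with Hba-a1 at -2.64. Whether the alveolar type 1-like cluster is the whole cause of the alveolar type 1 difference stays open. In tip-like cells alone, without that cluster, the median was 0.20 (camera adjusted p = 0.0398), though adjusted p = 0.465 with an estimated correlation. There 0 of 7 members were called, over all genes or over the list alone, and no random genes were split within tip-like cells. How much of the alveolar type 1 difference comes from cells of different kinds within a class stays open too. For G2/M genes the mix of clusters could be the cause, as the median in tip-like cells was -0.012.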

How the results depend on the processing

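The settings by subsets of clusters (without low-depth clusters, all distal clusters, tip-like or airway-like clusters alone in the Icam1 UMI comparison) were chosen after seeing the data. No paired analysis was possible between the sorts because the labels number only the Epcam+ Icam+ libraries. The cause was not tested where none is given.

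Between the sorts, the named genes of the epithelium kept their direction in 216 of 216 values and their call in 168 of 168, and those of the difference between classes kept 35 of 36 calls. The epithelial genes had been picked for the same direction against each library, and both sets as the largest differences called. These counts were thus largely set in advance and give little support. Called genes in epithelium ranged from 8014 (thinned) to 12145. Thinned counts gave 6474 in tip-like and 3764 in airway-like cells, with fewer UMIs. DESeq2 gave 4266 in airway-like cells and 220 for the difference between classes (640 at unadjusted p under 0.05). Genes that differed 2-fold numbered 3108 at 1 CPM and 470 at 50 CPM.

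With an estimated correlation the lists called fell from 10 to 0 in epithelium by camera (edgeR called members in each list), from 5 to 0 for the difference between classes and from 15 to 1 for the Icam1 UMI. That test had 1 or 2 residual degrees of freedom, so the lost calls decide neither way. In tip-like clusters the G2/M median reversed to 0.49. Without 1 of the Epcam+ Icam+ replicates, 27 and 25 of 34 list medians stayed within a fixed log2 distance of their value with both replicates. That distance takes no spread into account.

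Icam1 UMI calls, 166 in all, fell to 28 with DESeq2 and to 0 with edgeR without a library block (29 at unadjusted p under 0.05). Leave-one-out counts ranged from 14 to 221. Distal clusters alone gave 53, all but low-depth clusters 85, tip-like clusters 5 and airway-like clusters 4, with fewer cells in each. Named genes kept their direction in 264 of 264 values, which was largely set in advance, as they had been picked for the same direction in each library. The calls of these genes were kept in 102 of 192 values and lost in 68, and the others had no adjusted p in DESeq2. With 1 library left out 43 of 72 calls were lost. Lists called numbered 9 in tip-like clusters, with p53 targets and the NF-kB and TNF response among them, and 1 in airway-like clusters, the airway markers. No list held at an estimated correlation (lowest adjusted p = 0.465 and 0.826). Of the lists called by camera, the medians that reversed were airway markers without low-depth clusters (0.052, no longer called), TGF-beta response in tip-like clusters (-0.0011), dissociation stress in airway-like clusters (-0.042), S phase in tip-like (0.0075) and airway-like (0.0074) clusters and mitochondrially encoded genes in both (-0.015 and -0.024).

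Shares, as Epcam+ minus Epcam+ Icam+ in percentage points, depended on the clustering. Resolution 0.5 gave 15.4 for epithelial (18.1 in the report's setting), -15.2 for immune-like (-17.1) and 10.4 for airway-like cells (4.58), with no alveolar type 1-like cluster. Resolution 2 gave 6.69, -8.52 and 19.4, with 38.1 for tip-like (35.0) and -30.5 for alveolar type 1-like cells (-23.1). Scaling within libraries gave 22.03 for epithelial, -8.30 for immune-like and -3.83 for airway-like cells, a reversal. With doublets kept they were -16.9 for immune-like, 37.3 for tip-like, 10.5 for airway-like and -19.8 for alveolar type 1-like cells. The stricter filter gave -8.03 for immune-like and -7.06 for alveolar type 1-like cells and reversed tip-like (-16.9) and airway-like cells (-0.996).

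Unthinned, the difference in S phase was 14.1 (18.5 thinned) and in G2/M 14.6 (10.3), the share with an Icam1 UMI reversed from -4.29 to 5.92, and that with an Epcam UMI went from 1.36 to 4.65, as deeper cells show more genes. Over all barcodes the Icam1 difference went from -32.3 to -8.15 CPM and the Epcam difference reversed from -88.8 to 122 CPM, with immune-like cells included.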

Other observations

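In the Epcam+ library 300 cells formed an unnamed cluster, pooled with the epithelium for its 3 raised airway markers. Macrophage and mast cell genes (Cpa3, Cma1, Lyz2, C1qb) were among its leading genes. Its median depth was 35560 UMIs, 1.33 times the median of that library. No cell of the Epcam+ Icam+ libraries fell in this cluster, and whether its barcodes hold single epithelial cells was not tested. Low-depth barcodes formed 3 more clusters among the epithelial cells, with 457, 360 and 347 cells, and their mitochondrial shares were 0.198%, 3.75% and 0.369%. Globin UMIs in epithelial cells numbered 490 and 6103 in the Epcam+ Icam+ libraries and 83038 in the Epcam+ library.

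Icam1 in the macrophages moved the other way from the epithelium, with a log2 fold change of -0.39 (edgeR adjusted p = 0.0392). Of the 166 genes called between cells with and without an Icam1 UMI, 123 were also called between the sorts in the same direction and 37 in the opposite one, with 70 higher in each comparison against 38.1 for independent lists and 53 lower against 34.9. The Epcam+ Icam+ and Epcam+ cells enter the comparisons alike, so these are not independent measurements.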
